A study of Homo sapiens and Mus musculus with 25 samples.

How the data were processed

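The table analysed holds SHAPE-MaP data of hFAST from 3 libraries of H9 cells (NAI, DMSO and DC), 1 per treatment. Per the labels' protocols, RNA was reverse transcribed with manganese and primers for hFAST, amplified by nested PCR and sequenced after size selection of the libraries. No molecular identifiers are mentioned there, so reads are not independent molecules and intervals of mutation rates cover counting error only. Per the submitters' processing notes, bcl2fastq 2.17.1.14, Bowtie2 2.1.0 and the build hg19 were used for these samples. The program that counted mutations is not given in the sources used here. Per the file headers, the table has read depth and mutation rate for a background, a reagent and a denatured library. These were taken as DMSO, NAI and DC from the protocol wording and from the formula in the header, in which the background is subtracted and the denatured rate divides. DC is abbreviated in the columns as in the labels, while the names DMSO and NAI do not appear there. Because rates of the reagent library were mostly below background, the text writes "the library labelled NAI" where a direction is drawn.

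The deposited depths are counts of reads per nucleotide, with no normalization. The deposited DMSO and DC mutation rates are a fraction of those reads, as is the NAI rate, which has a missing mark at 1 nucleotide without reads. Rate times depth was within 0.0348 of a whole number at every nucleotide, so mutated reads were recovered by rounding. The authors deposited reactivity as a score, the NAI minus DMSO rate divided by the DC rate, with a standard error. Their normalized reactivity is that score times a constant, and how the constant was set is not given in the sources used here. It has no value at 28 nucleotides, 26 of which have a DC rate of 0. The other 2 are those with a DMSO rate above 5%. Negative scores were kept by the authors. The 6 other columns were not used.

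Depth per nucleotide ran from 0 to 74641 reads in NAI, 3 to 37034 in DMSO and 1 to 38326 in DC, and the sums over nucleotides were 14668783, 10411217 and 11170482. At the 525 nucleotides with at least 1000 reads in each library, the lowest depths were 1021, 1268 and 1320, at which a count of 0 allows up to 0.294%, 0.237% and 0.227%. Shares have 95% Wilson intervals, and the limit for a count of 0 is 3 counts. Mutated and unmutated reads of 2 libraries were compared at each nucleotide by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over nucleotides within each of the 3 comparisons and a threshold of 0.05. Such tests compare 2 libraries, not 2 conditions. Log2 ratios used 0.5 added reads. Reactivity by base and at unpaired against paired nucleotides was tested by permutation over all 547 circular shifts of the labels against the profile, two-sided, with adjustment over the 2 bases tested. Nucleotides along an RNA are not independent replicates. Windows of 51 nt with at least 26 values were compared with the most extreme window of 10000 shuffles of nucleotides and of blocks of 10 nt. Intervals of window medians come from 2000 bootstrap draws.

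Structures were computed with ViennaRNA 2.7.2 at 37 °C, from sequence alone and with reactivities as pseudo-energies (slope 1.8, intercept -0.6). Negative reactivities were set to 0 and missing ones left out. Energies with reactivities include the pseudo-energies and are not compared with those from sequence. A helix is a bulge-free stack of at least 4 bp with a mean pairing probability of at least 0.8. A low-reactivity low-entropy region has at least 20 nt at which the 51-nt medians of reactivity and of Shannon entropy are both below the overall medians. As controls, the fold was repeated with 99 shifted profiles, the same 99 shifts of the profile without division by DC, 99 profiles permuted within each base and a profile of 0. The profile without division by DC had a scale of its own and values at 546 nucleotides, against 519 in the deposited one. It includes nucleotides 283 and 486, which have no deposited normalized reactivity. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.

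The items named were fixed by rule before the data were examined: the 10 highest reactivities with a standard error under 0.5 of the value and at least 1000 reads in each library, the 3 lowest and 3 highest non-overlapping windows, helices of at least 6 bp with a probability of at least 0.9 (up to 10), up to 8 low-reactivity low-entropy regions and the 5 highest DMSO rates. Some items that this rule names are not reported here. The 7 helices shared by 3 folds were added after the values were seen. The planned tests and most alternatives (depth minimums of 1000 and 5000, a 2-fold minimum, Bonferroni correction, the ends left out, other scalings, window widths and fold settings) were also fixed before the data were examined.

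The functions were tested on simulated data with 200 changed nucleotides among 547. Simulated reads were drawn independently, which amplified reads are not, so the shares recovered and called hold for independent reads only. For NAI against DMSO, 40.3% of 1.5-fold, 65.7% of 2-fold and 87.9% of 4-fold changes were recovered, with 1.44% of unchanged nucleotides called. For DC against DMSO the shares were 34.3%, 73.1% and 90.9%, with 0.288% called. For NAI against DC they were 43.3%, 71.6% and 92.4%, with 1.15% called. The shift test passed the threshold in 2% of 100 simulated profiles without a difference and 97% of those raised by 0.5 SD at unpaired nucleotides. Gene names come from a table for GRCh38.p14, whose build differs from hg19, so no genomic positions are given and nucleotides are numbered along hFAST. The comparison by exon was left out because no genome was used, and 22 samples were not analysed here.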

Results

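The structure of hFAST, a human long noncoding RNA, was probed by SHAPE-MaP in H9 cells, an established line of human embryonic stem cells. FAST is a synonym of FOXD3-AS1, a long noncoding RNA gene that lies beside FOXD3, which encodes a transcription factor of pluripotent cells. In SHAPE-MaP a reagent acylates the ribose of flexible nucleotides, and reverse transcription with manganese writes each adduct into the cDNA as a mutation. There were 3 libraries, 1 per treatment. The first came from cells given NAI, a SHAPE reagent, at 100 mM for 10 min at 37 °C. The second came from cells given DMSO, the solvent, alone. The third, the denatured control (DC), came from RNA unfolded at 95 °C in 50% formamide and then modified. The profile covered 547 nucleotides (136 A, 147 C, 170 G and 94 T, with U written as T). Median depth per nucleotide was 16533 reads in the library labelled NAI, 14293 in DMSO and 16944 in DC. Depth was at least 1000 in all 3 libraries at 525 nucleotides, from nucleotide 12 to nucleotide 536. At these median depths a count of 0 allows a rate of up to 0.0181% in NAI, 0.0210% in DMSO and 0.0177% in DC. There were no replicates, so each test below compares libraries and not conditions. Intervals of mutation rates cover counting error in reads only. Those of class shares and window medians are taken over nucleotides, which are not independent replicates, and leave out counting error. The 22 RNA-seq samples of the series were not analysed here.

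**Figure D1:**
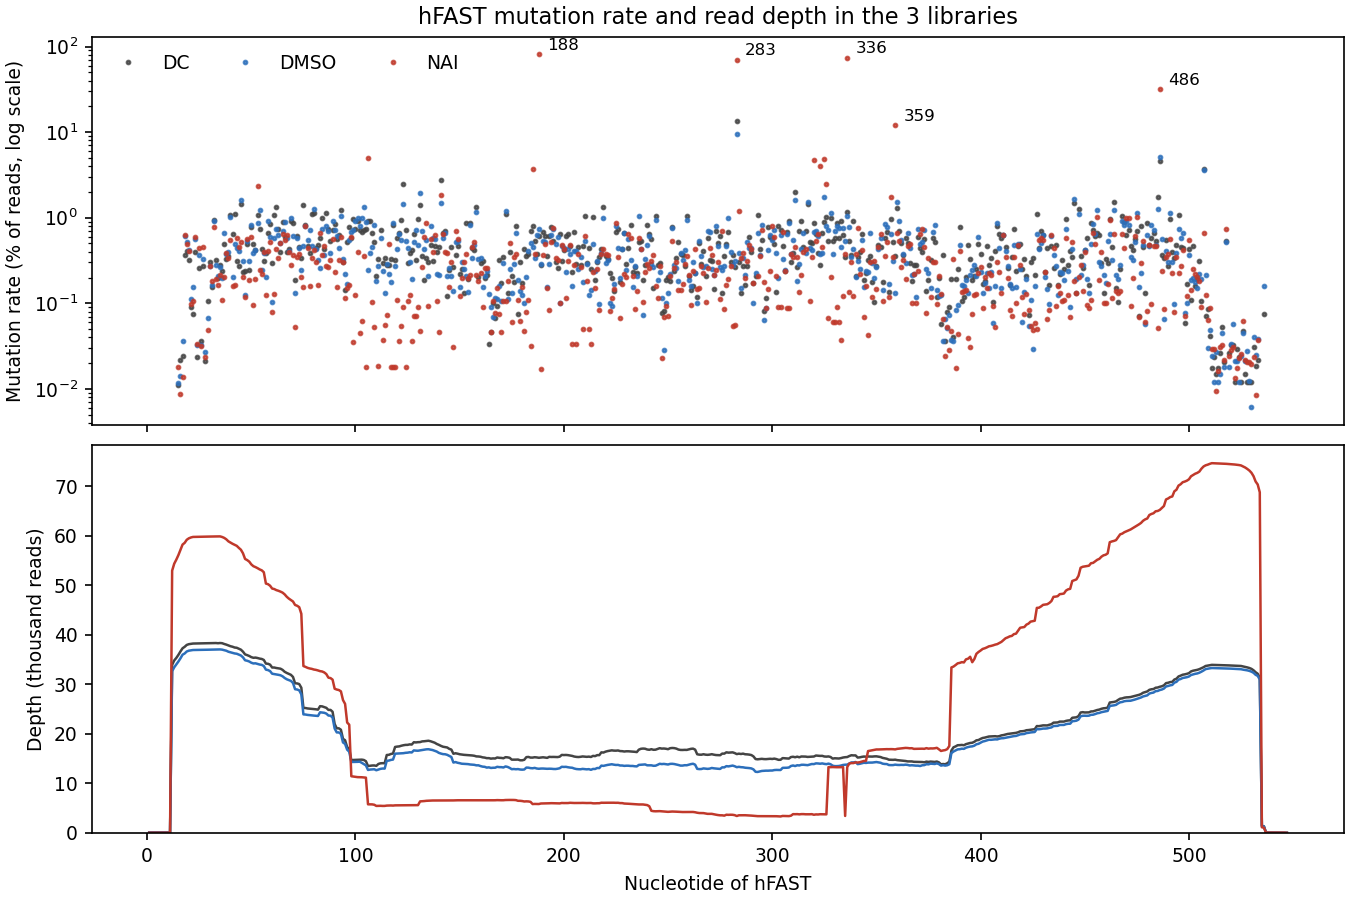
Mutation rate (percent of reads, log scale, upper panel) and read depth (in units of 1000 reads, lower panel) along hFAST in the NAI, DMSO and DC libraries; rates of 0 and rates at depths under 1000 are not drawn. The 5 labelled nucleotides exceed 10% in the library labelled NAI, and its depth falls to a median of 6006 reads between nucleotides 98 and 385.

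The comparison of NAI with DMSO asks which hFAST nucleotides the reagent modified in cells. Most of hFAST went the other way: the median mutation rate at the 525 nucleotides was 0.198% in the library labelled NAI and 0.324% in DMSO. The NAI rate was higher at 31 of the 546 nucleotides tested and lower at 184 (Fisher's exact test on reads, Benjamini-Hochberg adjusted p under 0.05). The 31 included sites with very large rates. Nucleotide 188, a G in AAAACCGGCGGCGGAGCGGGT (nucleotides 178 to 198), was mutated in 81.0% of NAI reads (95% Wilson interval 80.0 to 82.0%) and in 0.742% of DMSO reads (0.608 to 0.905%). Nucleotide 336, a G in GGGAGCGCCGGCCTCACCAGA (326 to 346), was mutated in 74.4% of NAI reads (73.6 to 75.1%) and 1.05% of DMSO reads (0.895 to 1.24%). Nucleotide 359, an A in AAGGAGCACGAGGGGAGGAGT (349 to 369), stood at 12.1% against 0.131%. Among the lowered sites, nucleotide 131, a G in the predicted apical loop of a GC-rich hairpin, had 3 mutated reads of 6348 in NAI (0.0473%, 0.0161 to 0.139%) and a DMSO rate of 1.94% (1.74 to 2.16%). By base, 35 of 87 T residues were lower and 1 was higher, while 22 of 127 A residues were lower and 4 were higher. The counts were 19 higher and 113 lower with a Bonferroni correction. They were 11 and 89 of 258 tested (4.26% and 34.5%, against 5.68% and 33.7% of 546) without nucleotides 98 to 385, a setting chosen after the depths were seen.

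The next 7 nucleotides by reactivity were far closer to background. In the stretch CGCTGCGGCCTGGGAGGGGAG (310 to 330), nucleotides 320, 323 and 325 had NAI rates of 4.71%, 4.02% and 4.89% and DMSO rates of 0.677%, 0.380% and 1.77%. Their adjusted p-values in Fisher's exact test were 3.61e-53, 1.30e-57 and 6.23e-23. Nucleotide 325 was also among the 5 highest DMSO rates. Nucleotide 106, an A between C runs in AGACCCCCCCACCCAGGCTGG (96 to 116), reached 4.98% in NAI and 0.244% in DMSO. Nucleotide 185, a G, reached 3.68% and 0.453%. Nucleotide 387, an A in the AU-rich stretch GGAAATAATTAGTGAAATATT (377 to 397), had 0.328% in NAI and 0.0365% in DMSO. Nucleotide 276, a G in a predicted hairpin loop, had 0.707% and 0.242%. Its adjusted p was 0.000452 in Fisher's exact test, and it did not pass the Bonferroni correction. The depth of the library labelled NAI at these sites ran from 3535 reads (nucleotide 276) to 33572 reads (nucleotide 387). Several sites lie at or beside abrupt changes in that depth. It fell from 11142 to 5759 reads at nucleotide 106 and rose from 17542 to 33390 at 386, beside 387. Shortly after 320, 323 and 325 it rose from 3733 to 13276, at 327. Whether the rates at these sites reflect modification was not tested. The other leading DMSO rates were at nucleotide 283, a G (9.43% in DMSO, 13.4% in DC, 70.4% in NAI), and nucleotide 486, a C (5.17%, 4.59% and 31.7%). Both lack a deposited normalized reactivity.

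The comparison of DC with DMSO asks how far the reagent raises mutation when hFAST is unfolded. The denatured RNA showed a modest rise: the rate was higher in DC at 120 of 547 nucleotides and lower at 53 (Fisher's exact test, adjusted p under 0.05). Larger shares of A and T than of C and G residues were higher. Of the A residues, 34 of 127 were higher and 6 lower, and of the T residues, 29 of 87 were higher and 6 lower. G residues were split, with 30 of 166 higher and 21 lower, and C residues had 27 of 145 higher and 20 lower. The median log2 ratio of DC to DMSO was 0.36 at A, 0.32 at T, 0.08 at C and -0.03 at G. The A and T median exceeded that of G and C by 0.32 (two-sided permutation over all 547 circular shifts, adjusted p = 0.00548 over 3 ratios). The same difference was -0.15 for NAI against DMSO (permutation, adjusted p = 0.177) and -0.38 for NAI against DC (adjusted p = 0.0329). That test was chosen after the rates by base were seen. Over all bases the median rate was 0.376% in DC, and counts with at least a 2-fold difference were 62 higher and 11 lower.

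The comparison of NAI with DC asks which nucleotides are less accessible in cells than in unfolded RNA. The rate in the library labelled NAI was lower than in DC at 246 of 546 nucleotides and higher at 52 (Fisher's exact test, adjusted p under 0.05). T residues stood out, with 59 of 87 lower and 1 higher and a median log2 ratio of -1.45. The median was -0.50 at A, -0.39 at C and -0.51 at G. The rate at nucleotide 188 was 132-fold higher in NAI than in DC, at nucleotide 336 it was 63.2-fold higher and at nucleotide 359 33.7-fold higher. Since the NAI rate was also below DMSO at 184 nucleotides, a rate under DC here does not separate protection in cells from a lower rate of that library as a whole.

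Normalized reactivity, the authors' deposited (NAI minus DMSO)/DC score times a constant, had a value at 519 nucleotides. Most of hFAST was in the low class: 428 nucleotides (82.5%, 95% Wilson interval 79.0 to 85.5%) were under 0.4, 35 (6.74%, 4.89 to 9.23%) were between 0.4 and 0.85, and 56 (10.8%, 8.40 to 13.8%) were at or above 0.85. The low class was largely below background, since 363 values (69.9%) were negative and the median was -0.519. By the deposited standard errors, 35 values were more than 2 SE above 0 and 209 were more than 2 SE below 0. The classes depend on which library is subtracted: with the DMSO and NAI columns exchanged, a setting added after the data were seen, 44.7% were low, 16.8% intermediate and 38.5% high. That setting turned the sign of the deposited values and kept their constant and their 519 nucleotides. The turned profile was not rescaled, so these shares also depend on the scale that was kept. At nucleotide 188 the reactivity was 299.1 ± 31.3 (deposited SE), at 336 it was 142.6 ± 10.7 and at 359 it was 76.1 ± 10.6. The next 7 ran from 30.1 ± 5.34 at nucleotide 323 to 7.99 ± 1.18 at nucleotide 325. Median reactivity was -0.359 at A, -0.472 at C, -0.563 at G and -0.855 at T. Neither A (0.285 above C and T together, adjusted p = 0.161) nor G (0.0818 above, adjusted p = 0.578) passed the shift permutation test. Without division by DC, the A difference was 0.500 and passed (permutation, adjusted p = 0.0219).

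Reactivity was lowest in a GC-rich 51-nt window. The lowest window, nucleotides 87 to 137 (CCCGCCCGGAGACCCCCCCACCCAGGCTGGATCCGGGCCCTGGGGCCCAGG, 82.4% G and C), had a median reactivity of -1.32 (bootstrap 95% interval -1.70 to -1.14). It held 37 nucleotides with a lower NAI than DMSO rate and 3 with a higher rate. It was 0.798 below the median of all nucleotides (permutation p = 0.000900 over 10000 shuffles, and p = 0.00970 when blocks of 10 nt were shuffled). With the columns exchanged and the scale kept, its median would be 1.32. By shuffled blocks the lowest window did not pass at either of the other widths run (permutation p = 0.0512 in windows of 25 nt and 0.0507 in longer ones). Depth of the library labelled NAI fell inside the window of 87 to 137, from 21827 to 11425 reads at nucleotide 98 and from 11142 to 5759 at nucleotide 106. A link between these falls and the low values was not tested. The next lowest windows were nucleotides 327 to 377 (median -0.861, -1.22 to -0.354) and 436 to 486 (-0.703, -0.961 to -0.437). The window of 327 to 377 begins where NAI depth rose from 3733 to 13276 reads. The windows of nucleotides 217 to 267 (-0.285, -0.692 to -0.0884) and 6 to 56 (-0.334, -0.541 to 0.0282) were among the 3 highest windows.

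**Figure D2:**
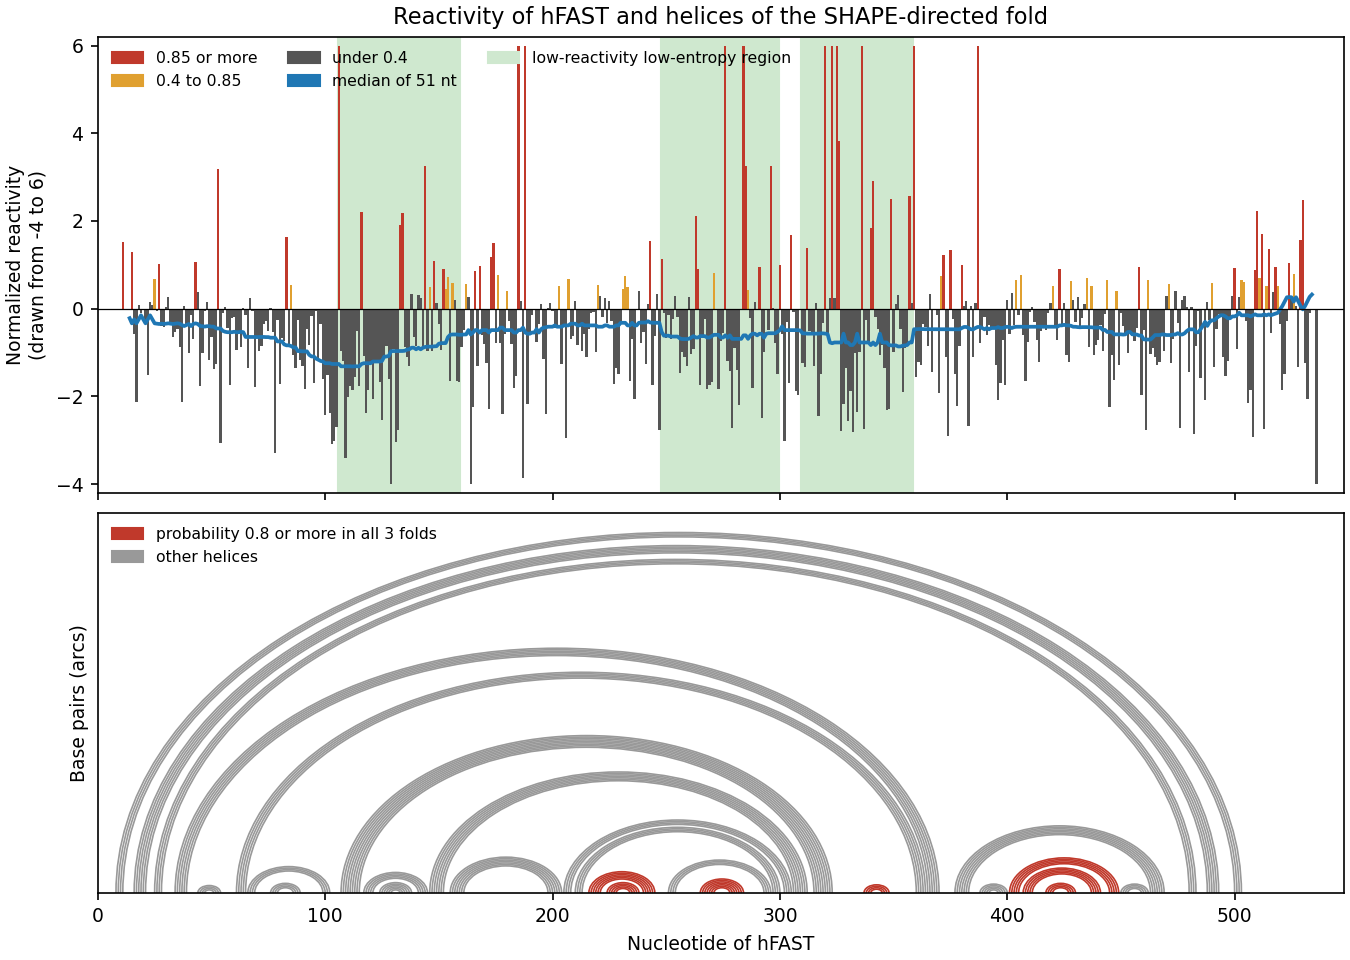
Normalized reactivity per nucleotide (upper panel, bars drawn from -4 to 6 with values beyond drawn at those limits, line for the median of 51 nt, shading for the 3 low-reactivity low-entropy regions) and base pairs of the 26 helices of the SHAPE-directed fold (lower panel, arcs). Red arcs mark the 7 helices with a mean probability of at least 0.8 in all 3 folds, and the shaded regions lie between nucleotides 106 and 358.

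Unpaired nucleotides of the fold computed from sequence alone (-213.7 kcal/mol, 162 base pairs) were slightly more reactive than paired ones. The median was -0.430 at 202 unpaired and -0.640 at 317 paired nucleotides. The area under the curve was 0.564 (p = 0.0256, permutation over all 547 circular shifts, two-sided), while the difference in medians, 0.209, had p = 0.0530. Ranked within each base the area was 0.550 (permutation p = 0.0786), and with a pair distance of at most 300 nt it was 0.558 (p = 0.0530), so neither passed.

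With the reactivities as pseudo-energies, hFAST was predicted to fold into a long-range domain around local hairpins. The fold had 171 base pairs, 105 of them shared with the sequence-only fold, and 26 helices of at least 4 bp with a mean pairing probability of at least 0.8. The longest helix paired CCCAGGCTG (107 to 115) with CGGCCTGGG (315 to 323) at a probability of 0.903. Its 3′ arm holds nucleotides 320 and 323, with reactivities of 10.8 and 30.1. Inside it, 146 to 152 paired with 306 to 312 (7 bp, 0.991) and 155 to 161 with 198 to 204 (7 bp, 0.947). The 3′ part formed a separate domain closed by 377 to 383 with 463 to 469 (7 bp, 0.974). Over longer distances, 16 to 21 paired with 488 to 493 (6 bp, 0.971), and 34 to 39 paired with 365 to 370 (6 bp, 0.992). Local stems were 265 to 271 with 278 to 284 (7 bp, 0.994, arms GCCTGCC and GGCAGGC), 216 to 221 with 240 to 245 (6 bp, 1.000) and 124 to 129 with 133 to 138 (6 bp, 0.941). Median reactivity in the arms ran from -1.41 in the 265 to 284 hairpin to -0.193 in the helix of 16 to 21 with 488 to 493. The 3′ arm of the 265 to 284 hairpin also holds nucleotide 283, which has no normalized reactivity and is not in that median, and nucleotide 284, singled out after its values were seen, with a reactivity of 5.99 (1.19% in NAI and 0.383% in DMSO).

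The number of helices depended on how the reactivities entered the fold. It was 14 without reactivities, 9 with negative values treated as missing, 4 without division by DC and 14 with a slope of 2.6 and an intercept of -0.8. Of the 26 helices, 7 also had a probability of at least 0.8 both without reactivities and with negative values as missing. These were the hairpin stem 265 to 284, the nested stems 216 to 245 and 224 to 238 (TGCAC with GTGCA), the short hairpin 337 to 348, and the 3 stacked stems 401 to 449, 407 to 441 and 417 to 430. Of the 9 helices described above, 5 had a probability of at least 0.8 from sequence alone, 5 with a pair distance of at most 300 nt, 4 with the steeper slope, 2 with negative values as missing and 1 without division by DC. The pair distance limit excludes by construction the helices of 34 to 39 with 365 to 370 and of 16 to 21 with 488 to 493. The stem of 216 to 221 with 240 to 245 was at or above 0.879 in all 12 settings run on this fold. The helix of 107 to 115 with 315 to 323 had 0.861 from sequence alone, 0.605 without division by DC, 0.571 with the steeper slope, 0.00519 with the pair distance limit and 0.000324 with negative values as missing. The hairpin of 124 to 138 had 0.00649 with the pair distance limit. That of 265 to 284 had 0.768 without division by DC, in a profile that also includes nucleotide 283 of its 3′ arm. Of 99 profiles shifted along hFAST, 3 kept as many sequence-only base pairs as the measured 105 (median 50, permutation p = 0.04), and none gave 26 helices (highest 25, permutation p = 0.01, the smallest that 99 shifts can give). A flat profile of 0 at every nucleotide kept 96 sequence-only base pairs and gave 16 helices, and the measured profile without division by DC kept 42, which 60 of 99 shifts of that profile reached (median 49, permutation p = 0.61), and its 4 helices were reached by 98 of 99 (median 16, permutation p = 0.99).

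**Figure D3:**
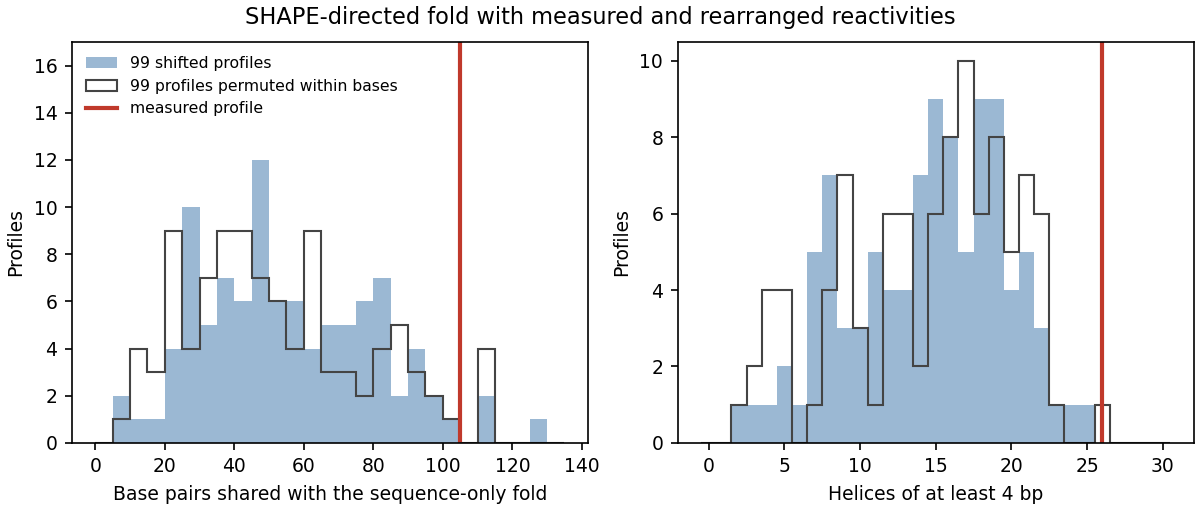
Number of base pairs shared with the sequence-only fold (left) and number of helices of at least 4 bp (right) in SHAPE-directed folds of 99 shifted profiles (filled bars) and 99 profiles permuted within each base (outline), counted as profiles on the y axis. The red line is the measured profile, with 105 shared base pairs and 26 helices.

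Regions where both reactivity and pairing entropy were low covered 28.3% of hFAST in 3 stretches. Both limits are medians of hFAST itself, so part of the RNA can fall below them whatever its structure. The entropy comes from the fold that used these reactivities, so it is not independent of them. Nucleotides 106 to 159 (median reactivity -0.966, 70.4% G and C) held the 5′ arm of the longest helix and the 124 to 138 hairpin, with 27 nucleotides lower and 3 higher in NAI than DMSO. The higher ones included nucleotide 106 (reactivity 12.0). This region starts at the fall in NAI depth at nucleotide 106. Nucleotides 248 to 299 (median -0.635) held the 265 to 284 hairpin, with 12 lower and 3 higher, including nucleotides 276 (reactivity 8.11) and 283 (70.4% in NAI). Nucleotides 310 to 358 (median -0.770, 75.5% G and C) held the 3′ arm of the longest helix, with 18 lower and 8 higher. The higher ones included nucleotides 320, 323, 325 and 336, with reactivities of 10.8, 30.1, 7.99 and 142.6. Abrupt changes in NAI depth lie inside this region, at 327, 335 and 336. Median NAI depth in the 3 regions was 6393, 3657.5 and 13280 reads. All 3 are low by their medians only and hold several of the highest reactivities of hFAST. With negative values as missing, nucleotides 248 to 292 and 328 to 358 were left, and 13.9% of hFAST was covered. The region of 106 to 159 was also absent without the nucleotides with NAI rates above 10% (15.7% covered) and with the steeper slope (18.5%), and windows of 25 nt gave 108 to 141 and 245 to 282 (13.2%).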

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

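In this part the test of diluted rates was set before its value was seen, while those on ratios to DC, ranks of the DC rates and matching read numbers were chosen after the rates and depths had been seen. The read depth of the library labelled NAI, a column used in the report only as a denominator, changed abruptly between neighbouring nucleotides where DMSO and DC changed far less. The log2 step was -0.93 at nucleotide 98, -0.95 at 106, 1.83 at 327, -1.96 at 335, 1.96 at 336 and 0.93 at 386. At 327, 335 and 336 the depth in DMSO and DC changed by no more than 1.01-fold, and at 386 it rose 1.16-fold in both. At 98 it fell 1.15-fold in DMSO and 1.16-fold in DC, and at 106 it fell 1.07-fold in both. Between the outermost steps the median depth was 6006 reads in NAI, 13618 in DMSO and 15411.5 in DC, against 54343, 27643 and 28419 elsewhere.

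Mutation rates above 10% in the library labelled NAI were seen at nucleotides 188, 336 and 359, and at 283 and 486, which were set apart by their high DMSO rates. At 188 and 336 the NAI rate was at least 63.2-fold above that of reagent-treated unfolded RNA, whose rate did not differ from DMSO by the test. These 2 sites were grouped by that DC result, and both are G. Over all G residues the median log2 ratio of DC to DMSO was -0.03, so a DC rate near DMSO cannot count against high flexibility there. High flexibility in cells therefore stays open as the cause at 188 and 336. It also stays open at 359 (33.7-fold, with DC 2.74-fold above DMSO, Fisher's exact test, adjusted p = 0.000767) and at 283 (5.25-fold, with DC 1.42-fold above DMSO, adjusted p = 6.62e-24). At 486 the NAI rate was 6.91-fold above DC and 6.14-fold above DMSO. The DC rate there was below that of DMSO (4.59% against 5.17%, Fisher's exact test, adjusted p = 0.00548), so the 2 values point different ways and leave flexibility open. Templates that differ from the reference may contribute at 283 and 486, whose rates ranked 2 or better in DC, although the share differed between libraries (70.4% in NAI, 13.4% in DC and 9.43% in DMSO at 283). At nucleotide 336, 9878 mutated reads stood beside 9873 reads missing at 335 and 9543 reads gained at 327, the smallest being 96.6% of the largest, so a single group of molecules that starts near 327 and lacks nucleotide 335 is a candidate explanation there. For 188 and 359, a few amplified molecules cannot be told apart from other causes, because the median log2 NAI to DMSO ratio between 188 and 359 was 0.15 above that elsewhere, within the spread of shifted positions (permutation p = 0.569). The rule set beforehand counted a ratio at or above that elsewhere against this explanation. That verdict is not drawn here because of the spread.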

How the results depend on the processing

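Of 120 alternative values of the planned results, 76 kept their direction, side of the threshold or range, and the rest follow; the cause was not tested unless stated. No paired analysis was possible because there was 1 SHAPE-MaP library per treatment, and for the same reason no replicate could be left out. Fewer nucleotides passed stricter rules by construction. With Bonferroni correction there were 19 higher and 113 lower in NAI than DMSO, 61 and 17 in DC than DMSO, and 31 higher in NAI than DC. With a 2-fold minimum there were 62 higher and 11 lower in DC than DMSO, and 24 higher in NAI than DC. Settings chosen after seeing the data were those without nucleotides 98 to 385, without NAI rates above 10%, without the NAI library, with negative values as missing, and with the DMSO and NAI columns exchanged. Exchanged columns, without rescaling, gave 44.7% low, 16.8% intermediate and 38.5% high, and the lowest window, with its sign turned, was reversed to 0.798 above the overall median. Without 98 to 385, where fewer nucleotides were tested, counts were 11 and 89 of 258 (NAI, DMSO), 64 and 26 (DC, DMSO), 24 and 118 (NAI, DC). Without division by DC, the low class was 85.7% and the high class 8.24%, A exceeded C and T by 0.500 (permutation, adjusted p = 0.0219), G was reversed at -0.227 and 4 helices were left. The 2 to 8% rule gave 88.2% low and 5.78% high. With DC minus DMSO and no NAI library, the low class was 74.4% and the intermediate 13.5%, A minus C and T was -0.0612 (adjusted p = 0.282) and G -0.116 (adjusted p = 0.0475, past the threshold), both reversed, the area for unpaired nucleotides was 0.536 (permutation p = 0.190), the lowest window, in another place (325 to 375), minus the overall median was -0.141 (p = 0.117), 15 helices formed and low regions covered 20.5%. At unpaired nucleotides alone G was reversed at -0.113. The lowest window passed by shuffled nucleotides at both other widths, but not by shuffled blocks (permutation p = 0.0512 and 0.0507). The area was 0.558 (permutation p = 0.0530) with pair distances of at most 300 nt and 0.550 (p = 0.0786) by ranks within bases, in a range of 0.536 to 0.591 over all alternatives. Helices numbered 14 with slope 2.6 and intercept -0.8, 14 without reactivities and 9 with negative values as missing. Low regions covered 18.5% with the steeper slope, 13.9% with negative values as missing, 15.7% without NAI rates above 10%, and 13.2% and 23.8% in shorter and longer windows. The rescaling of NAI to DC was not run, because the median deposited score was -0.226 and gave no positive factor, and the comparison by exon was not run. Depth limits the ends of hFAST (22 nucleotides under 1000 reads) and, in NAI, nucleotides 98 to 385.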

Other observations

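In this part, the tests of protection and of spread were chosen after the rates had been seen, the shifts of the profile without DC after its fold had been seen, and the helix count in permuted profiles replaced the planned count of shared base pairs after both values had been seen, while the tests on exchanged columns, on the profile of 0 and on base pairs shared by shifted profiles were set before. The denatured and in-cell libraries differed most at T residues: the median log2 ratio to DMSO was 0.32 in DC and -0.98 in the library labelled NAI. At A residues the medians were 0.36 and -0.31, at C 0.08 and -0.34, and at G -0.03 and -0.48. The hairpin of nucleotides 224 to 238 had a median reactivity of 0.452 in its 5-nt loop and -0.505 in its arms, and that of 417 to 430 had -0.416 in its loop and 0.0128 in its arms. Among the other hairpins of the 26 helices, the loop was also lower at 124 to 138 (-2.77 against -1.09) and higher in the rest, in some by little. These differences were not tested. The hairpins come from the fold that used these reactivities, so a loop more reactive than its arms is partly built in.

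The library labelled NAI had a lower mutation rate than DMSO over most of hFAST. Protection by structure or protein gives no rate below that of untreated RNA, so it does not by itself account for the 33.7% of nucleotides below DMSO, although these calls cover counting error only and 9.69% of nucleotides were below DMSO in DC. Few template molecules behind that library cannot be told apart from modification that varies with structure in cells, since either would widen the spread of log2 NAI to DMSO ratios beyond counting error, which was 2.17 times that of DC to DMSO (bootstrap 95% interval 1.70 to 2.61, over 428 nucleotides), and each treatment had 1 library. Exchanged DMSO and NAI columns cannot be told apart from the order used: the area under the curve of the DMSO over DC rate at unpaired nucleotides was 0.454, on the side away from an exchange but within the spread of shifts (permutation p = 0.110). The rule set beforehand counted an area on that side against an exchange, with no limit on p. That verdict is not drawn here because of the spread. The reactivity itself was higher at unpaired nucleotides (area 0.564, permutation p = 0.0256), which an exchange would turn, but its area ranked within bases (0.550, p = 0.0786) and those of NAI over DC (0.530, p = 0.371) and NAI over DMSO (0.558, p = 0.0603) did not pass, so an exchange is not excluded.

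The SHAPE-directed fold had 26 helices and the sequence-only fold 14, but without division by DC the count was 4, which 98 of 99 shifts of that profile reached (permutation p = 0.99), and with negative values as missing it was 9. A pairing bonus given alike to every nucleotide is argued against as the whole cause of the 26, since a profile of 0 at every nucleotide gave 16 helices. That profile has no positive or missing values, so it does not test a bonus given to most nucleotides only. Reactivity levels that differ between the 4 bases cannot be told apart from other causes, because 1 of 99 profiles permuted within each base reached 26 helices (permutation p = 0.02) while 4 of 99 kept as many as the 105 sequence-only base pairs (permutation p = 0.05, not under the threshold). Reactivities that follow the base pairs of hFAST cannot be told apart from chance, because the 2 forms of the profile differ: 3 of 99 shifts of the profile divided by DC kept as many sequence-only base pairs as its 105 (112 with the 2 to 8% rule and 96 with the profile of 0), while 60 of 99 shifts of the profile without that division kept as many as its 42 (permutation p = 0.61). The 2 forms differ in scale and in the nucleotides included as well as in the division by DC.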
